A study of Drosophila melanogaster with 36 samples.

How the data were processed

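The values were those deposited for 36 one-colour Affymetrix arrays, 3 for each of 12 groups of 4 genotypes and 3 days. Per the labels, each RNA sample came from 20 fly heads, and total RNA was labelled with biotin by the manufacturer's protocol. The deposited log2 values, 1 per probe set and array, had been processed by the authors with R 2.11.0, per the submitters' processing notes. The background correction, summarization and normalization behind them are not given in the sources used here. No value was missing, the columns were not centred by gene, and the arrays did not share one distribution. Array measurements have no read depth, and signal over background and the number of arrays limit their precision.

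Of 18952 probe sets, 183 were controls and 18769 were tested. By the platform annotation, 13647 of them carried 1 gene symbol, 402 several and 4720 none. Each of 11982 genes was represented by its probe set of the highest mean value over all arrays. The genes ft and w were not analysed here. Of the genes written into the lists, those without a representative were not used here.

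All arrays entered one linear model with a mean for each group, fitted with limma 3.58.1 in R 4.3.3. Moderated tests of 20 contrasts used a residual of 24 degrees of freedom and a prior of 6.49. P-values were adjusted over the tested probe sets of each contrast by the Benjamini-Hochberg method, with a threshold of 0.05, and every adjusted p of a gene comes from this limma test. A probe set past the threshold is called higher or lower. The numbers of the replicates were ignored in this model. A call shared by the polyQ lines passed the threshold in the same direction in both lines against both Control and Atro. For such overlaps, all groups, Control included, were simulated 20 times as unchanged, with independent noise and with comparisons that share the simulated Control. Each overlap was also set beside that of independent lists.

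The groups, model, contrasts, gene lists, named-gene rule and most alternatives were fixed before the data were examined. The rule took up to 8 of the largest rises and falls among genes past the threshold whose replicates did not overlap between the compared groups, which chance gives for 10% of genes with 3 against 3. Differences between changes had no such condition. It also took up to 4 members of each list with the smallest adjusted p, and Gug. A gene named by the rule in one comparison is followed in others, and genes outside the rule are marked where they appear. Of the 28 measured lists, which ones are described was decided after the tests were seen.

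Lists were tested with camera, which sets a list's genes against all others with a preset correlation of 0.01 between genes, and again with a correlation estimated from the data. Both were adjusted over the lists of a comparison. Of 560 tests of a list in a comparison, 178 passed with the preset correlation, 102 of them in the same direction in all 3 scalings. None passed with an estimated correlation, for which the unadjusted count under 0.05 was 25. The fry test asks whether a list's genes move one way on balance, without comparing them with other genes, and 69 tests passed by it.

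Alternatives were quantile and cyclic loess normalization of the deposited values, the brighter probe sets alone, a trended and robust prior, array weights, a fit of the compared groups alone, the replicate number as a block, and leaving out each replicate in turn. When a group lost an array, limma's pooled spread was kept. Added after seeing the data were a fit without the 6 arrays of outlying spread and, for shared calls, A66QC alone and the other pairings of the genotypes. The model was tested on simulated data of 18769 probe sets for A66QC against Control at day 14. It called 68% of 50 changes of 0.25 on the log2 scale, 96% of those of 0.5, 98% of those of 1, 100% of those of 2 and, as shared calls, all 100 probe sets lowered by 1 in both polyQ lines. Of its 293 calls in that comparison, 12 were unchanged probe sets. The simulated noise was independent between probe sets and arrays. These shares thus need not hold for the real arrays, which differ in spread as whole arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.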

Results

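RNA from fly heads was measured on 36 one-colour Affymetrix arrays, which carried 18769 probe sets for fly genes and 183 control probe sets. The flies had 4 genotypes, each sampled at days 0, 2 and 14 at 29 °C, with 3 arrays in each of the 12 groups. Control flies carried the eye driver GMR-Gal4 together with a temperature-sensitive Gal80 repressor. The other lines also carried a transgene of Atrophin, the fly protein encoded by Gug. The transgene was wild-type in the line called Atro and held an expanded polyglutamine (polyQ) stretch in the lines A66QC and A75QN. Development at 18 °C kept the transgene repressed, so day 0 marks newly eclosed flies before its induction. Array medians lay between 6.34 and 6.40 on the log2 scale and array SDs between 1.45 and 1.67. No background signal was used here, so a group mean under the highest of these medians is called near background, a limit set after seeing the data. The size of a difference from such a level is uncertain and may be understated. The SD of 6 arrays lay at least 5% off its group's median, and these are called the arrays of outlying spread, a limit chosen after seeing the data. Replicates correlated with r of 0.9952 to 0.9985 across probe sets, which are not independent replicates. No pair of columns held identical values. The labels do not tell whether replicates came from separate fly cultures, so p-values measure only the spread between these samples. The number of arrays limits the precision of every value.

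One technical measure set 6 arrays apart. The 24 probe sets for bacterial poly-A spike-ins averaged 13.2 to 13.4 on the A75QN arrays of days 2 and 14. They averaged 10.2 to 10.8 on the other 30 arrays. The hybridization controls differed by -0.0220 between the same sets of arrays. Every A75QN comparison at days 2 and 14 thus sets these 6 arrays against arrays with less spike-in signal, and that difference and the genotype cannot be told apart within it.

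**Figure D1:**
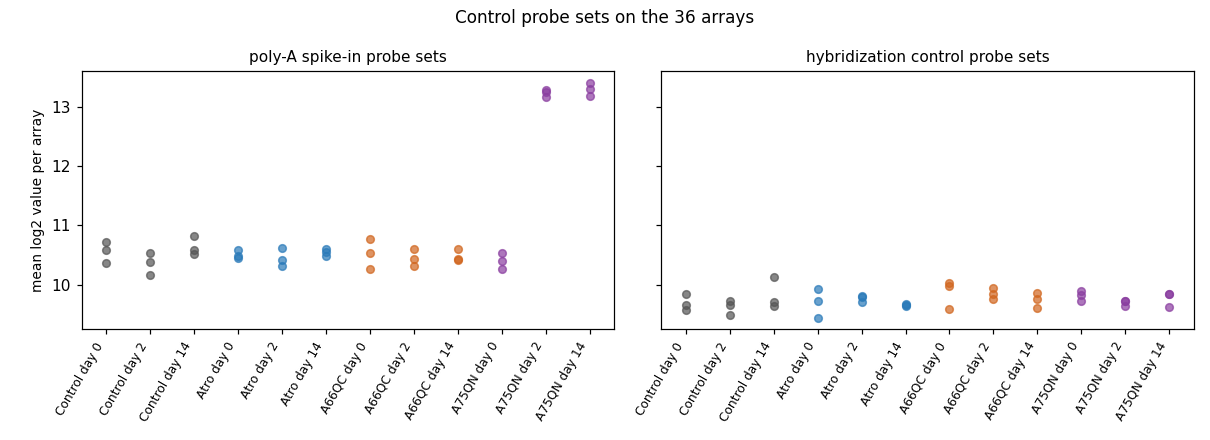
Mean log2 value of the poly-A spike-in probe sets (left) and of the hybridization control probe sets (right), 1 point per array, by genotype and day. The A75QN arrays of days 2 and 14 sit at 13.2 to 13.4 for the spike-ins, and all others between 10.2 and 10.8.

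Gug, the gene for Atrophin, was not called higher in any transgenic line on any day in the values as deposited. In Control its log2 level was 9.09 ± 0.12 at day 0, 8.88 ± 0.16 at day 2 and 8.97 ± 0.12 at day 14 (SD, n = 3). Against Control, Atro differed by -0.04 (SE 0.11, adjusted p = 0.980) at day 0, 0.10 (SE 0.11, adjusted p = 0.911) at day 2 and -0.0056 (SE 0.11, adjusted p = 0.995) at day 14. In A66QC the differences were -0.40 (SE 0.11, adjusted p = 0.0146), -0.12 (SE 0.11, adjusted p = 0.787) and -0.31 (SE 0.11, adjusted p = 0.0493) on the same days. A75QN differed by -0.35 (SE 0.11, adjusted p = 0.0477), 0.14 (SE 0.11, adjusted p = 0.662) and -0.16 (SE 0.11, adjusted p = 0.311). The lower call of A66QC at day 14 was lost with quantile normalization, with cyclic loess, without the arrays of outlying spread, without Control replicate 2 or 3, and without any 1 of the A66QC arrays. At day 2, Gug was called lower in A66QC with array weights or without the arrays of outlying spread. Both calls at day 0 were lost without Control replicate 2 or 3, or without replicate 1 or 2 of the line. Whether this probe set reads the transgenes is not given in the sources used here.

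Control flies show what age and the shift to 29 °C did without an Atrophin transgene. From day 0 to day 2, many muscle and some cuticle genes fell while sad, bw and DptB rose. CG7214 fell by 3.48 (SE 0.14, adjusted p = 1.98e-18), Vajk2 fell by 2.89 (SE 0.19, adjusted p = 2.55e-13) and Vajk3 fell by 2.79 (SE 0.21, adjusted p = 1.13e-11) on the log2 scale. Among eye pigment genes, se, an enzyme of red pigment synthesis, changed by -1.98 (SE 0.15) and st, a pigment precursor transporter, by -1.32 (SE 0.061), whereas the transporter gene bw changed by 1.63 (SE 0.10). Among named genes the largest rises were those of sad, an enzyme of ecdysone synthesis, at 3.53 (SE 0.071, adjusted p = 1.63e-26), the antimicrobial peptide gene DptB at 3.15 (SE 0.54, adjusted p = 4.49e-05), and Osi6 at 2.94 (SE 0.14, adjusted p = 1.07e-16). The levels of sad at day 0 and st at day 2 were near background. Of 20 muscle markers, 15 fell, 1 rose and 4 were not called (1 higher and 16 lower adjusted over the list alone), Mlc2 and Tm2 by -1.43 (SE 0.11) and -1.31 (SE 0.10). The muscle list had adjusted p = 2.06e-12 by camera, and adjusted p = 0.196 with an estimated correlation. Of 106 cuticle protein genes, 21 fell and 4 rose (4 higher and 21 lower adjusted over the list alone), among them Cpr49Ag at -2.24 (SE 0.11) and Cpr62Bb at -1.44 (SE 0.10). Their list had adjusted p = 0.00929 by camera, and adjusted p = 0.886 with an estimated correlation. That list call was also lost without Control day 0 replicate 1 or Control day 2 replicate 3. In all, 1998 probe sets were higher and 2166 lower at day 2 than at day 0. The GAPDH 3'-minus-5' log2 difference, a sign of RNA quality, was 1.94 ± 0.20 at day 0 and 2.41 ± 0.033 at day 2 (SD, n = 3).

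By day 14, many muscle, mitochondrial and synaptic genes had fallen in Control heads since day 0, and many immune and ribosomal protein genes had risen. CG7214 fell by 6.61 (SE 0.14, adjusted p = 2.9e-26), CG11458 fell by 5.11 (SE 0.13, adjusted p = 3.4e-24) and Cpr49Ae fell by 3.48 (SE 0.09, adjusted p = 6.54e-24), with CG7214 and CG11458 near background at day 14. Osi6 rose by 3.97 (SE 0.14, adjusted p = 1.5e-20), DptB by 3.71 (SE 0.54, adjusted p = 1.9e-06) and the antimicrobial peptide gene Mtk by 3.62 (SE 0.70, adjusted p = 0.000113). Of 39 genes of antimicrobial peptides and immune response, 26 rose and 13 were not called (26 higher and 0 lower adjusted over the list alone). Examples were grass, a protease upstream of Toll, at 0.94 (SE 0.075) and pirk, a negative regulator of the Imd pathway, at 0.92 (SE 0.088). This list had adjusted p = 0.000111 by camera, and adjusted p = 0.315 with an estimated correlation. Cytosolic ribosomal proteins rose in 27 of 34 cases (27 higher and 0 lower adjusted over the list alone), such as RpS20 at 0.63 (SE 0.083). They had adjusted p = 1.27e-07 by camera, and adjusted p = 0.731 with an estimated correlation. Muscle markers fell in 16 of 20 cases and rose in 1 (1 higher and 17 lower adjusted over the list alone). The calcium pump SERCA stood at -2.11 (SE 0.10) and Mlc1 at -1.75 (SE 0.10). For that list, camera gave adjusted p = 1.08e-13, with adjusted p = 0.241 with an estimated correlation.

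Oxidative phosphorylation genes fell in 50 of 76 cases and rose in 2 over the same interval (2 higher and 51 lower adjusted over the list alone), for example SdhB at -0.71 (SE 0.071) and ND-42 at -0.70 (SE 0.083). The list had adjusted p = 8.87e-12 by camera, and adjusted p = 0.418 with an estimated correlation. Neuron and synapse genes fell in 21 of 44 cases (1 higher and 22 lower adjusted over the list alone), with Sap47 at -1.14 (SE 0.11) and ChAT, which makes acetylcholine, at -0.71 (SE 0.089). They had adjusted p = 1.2e-05 by camera, and adjusted p = 0.820 with an estimated correlation. Cuticle protein genes fell in 28 of 106 cases and rose in 6 (6 higher and 28 lower adjusted over the list alone). Cpr49Ag stood at -2.64 (SE 0.11) and Cpr72Ec at -2.49 (SE 0.12), the former near background at day 14. Camera gave adjusted p = 1.15e-05 for them, and adjusted p = 0.241 with an estimated correlation. Trachea markers fell in 6 of 9 cases and rose in 1 (1 higher and 6 lower adjusted over the list alone), with the chitin-binding gene Gasp at -1.70 (SE 0.16) and the chitin deacetylase serp at -1.85 (SE 0.18). Their test gave adjusted p = 0.00238 by camera, and adjusted p = 0.241 with an estimated correlation. Altogether 3627 probe sets rose and 2277 fell. With quantile normalization 3460 rose and 3121 fell, and with cyclic loess 3419 and 3425. The share of rises was 61.4% as deposited and 52.6% with quantile normalization. GAPDH's 3'-minus-5' difference was 2.32 ± 0.074 at day 14, against 1.94 ± 0.20 at day 0 (SD, n = 3).

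Day 0 compares the lines at the time when the design has the transgene off. Whether a difference then came from the stocks or from the sampling of the flies was not tested. Atro heads held more message of the clock genes tim at 1.53 (SE 0.083, adjusted p = 9.72e-14), vri at 1.13 (SE 0.11, adjusted p = 1.09e-08) and per at 0.53 (SE 0.061, adjusted p = 4.86e-07). The second tim probe set gave 0.24. The tim difference of Atro from Control was -0.10 (SE 0.083) at day 2, by which tim had risen in Control by 1.37 (SE 0.083). At day 14 tim was again called higher in Atro, at 0.42 (SE 0.083, adjusted p = 0.00131). Atro heads at day 0 held less of Pepck2, an enzyme of gluconeogenesis, at -1.70 (SE 0.15, adjusted p = 1.19e-09), and of TkR86C, a tachykinin-type receptor, at -1.19 (SE 0.10). Of 28 proteasome genes, 22 were higher in Atro and 6 were not called (26 higher and 0 lower adjusted over the list alone). Rpn1 stood at 0.51 (SE 0.10), Rpn2 at 0.52 (SE 0.10) and Rpn3 at 0.56 (SE 0.11), and the calls of these 3 were lost in a fit of the 6 compared arrays alone. The proteasome list had adjusted p = 4.19e-20 by camera, and adjusted p = 0.666 with an estimated correlation. Of 13 clock genes, 3 were higher and 10 were not called (3 higher and 0 lower adjusted over the list alone), with adjusted p = 4.52e-05 by camera, and adjusted p = 0.666 with an estimated correlation. In all, 591 probe sets were higher and 230 lower in Atro, or 872 higher and 753 lower with quantile normalization. The count of 821 became 523 without Control replicate 1 and 490 without Atro replicate 3.

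A66QC heads at day 0 likewise held more tim, at 1.35 (SE 0.083, adjusted p = 1.01e-12), vri, at 1.20 (SE 0.11), and per, at 0.46 (SE 0.061), and less Pepck2, at -1.54 (SE 0.15, adjusted p = 1.15e-08), and TkR86C, at -1.28 (SE 0.10). The second tim probe set stood at 0.13. At day 2, tim was lower in A66QC than in Control, at -0.54 (SE 0.083). Neuron and synapse genes were lower in 28 of 44 cases, with none higher (0 higher and 32 lower adjusted over the list alone). Among them were the acetylcholine receptor subunit nAChRalpha7 at -0.65 (SE 0.10), the RNA-binding protein gene fne at -0.65 (SE 0.10) and the active zone gene Rim at -0.65 (SE 0.10). The list had adjusted p = 2.54e-14 by camera, and adjusted p = 0.736 with an estimated correlation. Altogether 469 probe sets were higher and 1569 lower, against 1305 higher and 1417 lower with quantile normalization. The total of 2038 became 974 without Control replicate 2, 1350 without Control replicate 3, 1162 without A66QC replicate 1 and 1259 without A66QC replicate 2.

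A75QN heads at day 0 stood apart from Control in Tektin-C, a microtubule protein gene of cilia and flagella, which was higher by 2.16 (SE 0.10, adjusted p = 7.68e-16), and in Cyp6a17, a cytochrome P450 gene, which was lower at -2.52 (SE 0.24, adjusted p = 5.54e-09). Pepck2 was again lower, at -1.53 (SE 0.15, adjusted p = 1.03e-08), as was TkR86C, at -1.18 (SE 0.10). Cuticle protein genes were higher in 16 of 106 cases and lower in 3 (16 higher and 4 lower adjusted over the list alone), with Cpr64Aa at 1.35 (SE 0.10) and Cpr92F at 1.37 (SE 0.14). In Control, Tektin-C and Cpr64Aa were near background. They had adjusted p = 1.79e-07 by camera, and adjusted p = 0.231 with an estimated correlation. In all, 370 probe sets were higher and 951 lower, or 774 higher and 905 lower with quantile normalization. The total of 1321 became 662 without Control replicate 2, 756 without Control replicate 3 and 656 without A75QN replicate 2. The GAPDH 3'-minus-5' difference at day 0 was 1.94 in Control, 1.90 in Atro, 2.03 in A66QC and 1.98 in A75QN. For actin it was 1.41 ± 0.26 in Control (SD, n = 3), and 1.67, 1.64 and 1.72 in these lines. For eIF4a it was 1.57 ± 0.22 in Control, and 1.69, 1.73 and 1.81.

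**Figure D2:**
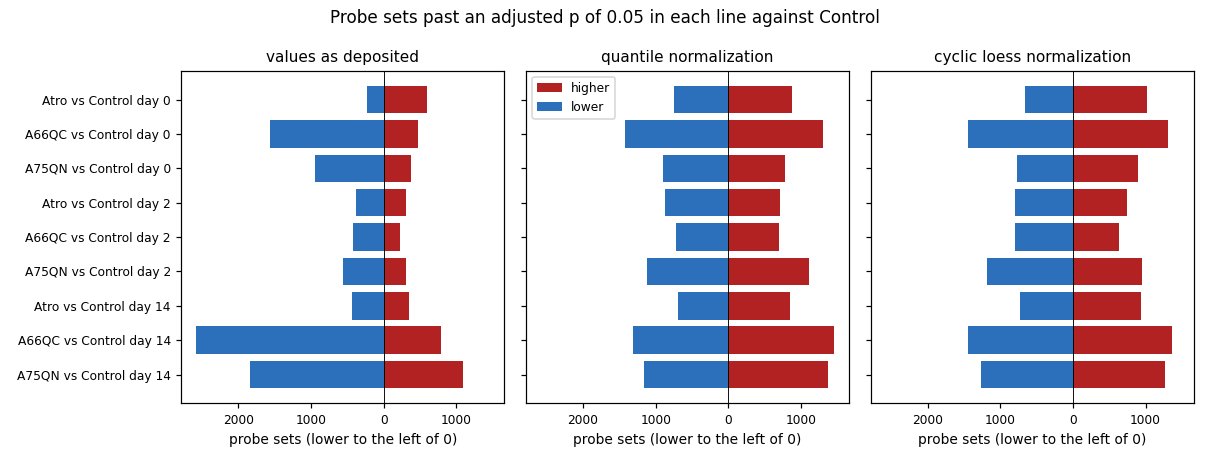
Number of probe sets past an adjusted p of 0.05 in each line against Control on each day, higher to the right and lower to the left of 0, for the values as deposited and after quantile or cyclic loess normalization. For A66QC at day 14 the 783 higher and 2582 lower probe sets of the deposited values became 1457 higher and 1309 lower with quantile normalization.

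The lines against Control at day 2 compare flies in which the design has the transgene on, so that any effect of it comes together with any difference between stocks. Induction itself was not seen in the Gug values, which as deposited were called higher in no line. After 2 days at 29 °C all 3 transgenic lines held less sad and bw message than Control, in which both had risen. The cuticle gene Cpr72Ec lay lower than in Control, at -4.40 (SE 0.12, adjusted p = 1.16e-22) in Atro, -3.67 (SE 0.12, adjusted p = 2.48e-20) in A66QC and -3.48 (SE 0.12, adjusted p = 6.06e-20) in A75QN. For sad the differences were -2.28 (SE 0.071), -2.14 (SE 0.071) and -2.20 (SE 0.071), and for bw -1.65 (SE 0.10), -1.76 (SE 0.10) and -1.18 (SE 0.10), all past the threshold. The second bw probe set gave -0.76, -0.70 and -0.49. Pepck2 differed by -2.22 (SE 0.15), -2.38 (SE 0.15) and -2.39 (SE 0.15). Muscle markers, which had fallen in Control by this day, were higher than in Control in 10 of 20 cases in Atro (14 higher and 0 lower adjusted over the list alone), 5 in A66QC (9 higher and 1 lower adjusted over the list alone) and 6 in A75QN (14 higher and 0 lower adjusted over the list alone). Mlp60A, a muscle LIM protein gene, stood at 0.76 (SE 0.11), 0.74 (SE 0.11) and 0.70 (SE 0.11). The camera test gave adjusted p = 5.97e-16, 7.71e-07 and 8.7e-09 for these lists, and adjusted p = 0.171, 0.997 and 0.922 with an estimated correlation. With quantile normalization 12, 9 and 14 of these markers were higher, and 1 was lower in A66QC. Tektin-C was higher by 1.84 (SE 0.10) in Atro and 2.15 (SE 0.10) in A75QN, while in A66QC and Control it was near background. At day 0 it had already been higher than in Control by 1.75 (SE 0.10) in Atro and 2.16 (SE 0.10) in A75QN, with Control near background then as well.

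At day 2, 304 probe sets were higher and 377 lower in Atro than in Control, 226 and 420 in A66QC, and 311 and 567 in A75QN. With quantile normalization these became 714 higher and 874 lower in Atro, 704 higher and 726 lower in A66QC and 1104 higher and 1119 lower in A75QN. The A75QN total of 878 was 533 without Control replicate 3 and 541 without A75QN replicate 3, and its arrays carried the higher spike-in signal. In A66QC, DptB was lower than in Control at -2.63 (SE 0.54, adjusted p = 0.00248) and Gnmt, a glycine methyltransferase, at -1.92 (SE 0.26, adjusted p = 5.97e-06). A75QN differed from Control in Gnmt by -1.48 (SE 0.26, adjusted p = 0.000290). The 646 probe sets of A66QC became 2955 without the 6 arrays of outlying spread and 5471 with array weights. The GAPDH 3'-minus-5' difference at day 2 was 2.41 in Control, 2.40 in Atro, 2.54 in A66QC and 2.28 in A75QN.

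Setting the polyQ lines against Atro compares the expanded with the wild-type transgene at the same age, together with any difference between these stocks. At day 2, both lines held less message of some immune genes than Atro. DptB was lower at -3.79 (SE 0.54, adjusted p = 0.000172) in A66QC and -2.87 (SE 0.54, adjusted p = 0.00151) in A75QN, and PGRP-SC2, a peptidoglycan recognition gene, at -1.78 (SE 0.29, adjusted p = 0.000980) and -1.86 (SE 0.29, adjusted p = 0.000156). At day 0, DptB stood against Control at 2.44 (SE 0.54, adjusted p = 0.00477) in Atro and 2.05 (SE 0.54) in A75QN, both called, and at 0.39 (SE 0.54, adjusted p = 0.683) in A66QC, and its mean was 9.80 in Atro against 7.75 in A66QC. The Atro call at day 0 was lost without Atro replicate 2, with array weights and in a fit of the 6 compared arrays, and that of A75QN without Control replicate 3 or A75QN replicate 1 or 2. The polyQ lines were not tested against Atro at day 0. Gnmt was lower at -2.13 (SE 0.26) and -1.69 (SE 0.26). In A66QC, 5 of 39 genes of antimicrobial peptides and immune response were lower and none higher (0 higher and 11 lower adjusted over the list alone), with adjusted p = 8.43e-05 by camera, and adjusted p = 0.749 with an estimated correlation. In A75QN, 11 were lower and 2 higher (3 higher and 18 lower adjusted over the list alone), with adjusted p = 3.13e-07 by camera, and adjusted p = 0.242 with an estimated correlation. BomS2, a Toll-induced peptide gene, stood at -0.95 (SE 0.15) there. The kinase gene Sik3 was higher in A66QC than in Atro by 1.19 (SE 0.12, adjusted p = 2.93e-07), while its second probe set gave 0.051. Sik3 had differed from Control by 0.85 (SE 0.12) in A66QC at day 0. A66QC had 20 probe sets higher and 77 lower than Atro, or 226 higher and 209 lower with quantile normalization. Its total of 97 became 41 without Atro replicate 3, and 58, 50 and 189 without A66QC replicate 1, 2 and 3. It became 2894 without the 6 arrays of outlying spread and 4538 with array weights. A75QN had 132 higher and 265 lower, or 486 higher and 545 lower with quantile normalization. Its total of 397 was 208 without Atro replicate 3, 244 without A75QN replicate 2 and 228 without A75QN replicate 3. 12 probe sets were called the same way in both polyQ lines against both Control and Atro. Paired otherwise, A66QC and Atro shared 59 calls against A75QN and Control, more than the polyQ lines did. All 12 calls of the polyQ lines were lower, among them Gnmt, phu, an alkaline phosphatase gene, and the tetraspanin gene Tsp42Eo. At day 0, phu had already been lower than in Control, at -1.22 (SE 0.18) in Atro, -1.26 (SE 0.18) in A66QC and -1.07 (SE 0.18) in A75QN. With quantile normalization 6 were higher and 29 lower.

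At day 14 the polyQ lines held much less message of several eye genes than Control did. Against Control, bw was lower at -3.34 (SE 0.10, adjusted p = 1.39e-22) in A66QC and -3.01 (SE 0.10, adjusted p = 1.63e-21) in A75QN. Its second probe set gave -1.02 and -0.90. In A66QC bw had been lower at day 0 as well, at -0.53 (SE 0.10). The corneal lens gene retinin was lower at -2.46 (SE 0.092, adjusted p = 1.77e-19) and -3.75 (SE 0.092, adjusted p = 1.92e-24). Pdh, a retinol dehydrogenase of pigment cells, stood at -2.45 (SE 0.092) and -2.38 (SE 0.092), and rdhB, another retinol dehydrogenase, at -2.39 (SE 0.09) and -2.43 (SE 0.09). Osi6 stood at -4.62 (SE 0.14) and -4.45 (SE 0.14), pkm at -3.83 (SE 0.10) and -3.64 (SE 0.10), and sad at -3.11 (SE 0.071) and -3.10 (SE 0.071). The glutamate transporter gene dmGlut stood at -2.25 (SE 0.07) and -1.91 (SE 0.07). The long noncoding RNA lncRNA:CR42646 was higher by 2.13 (SE 0.058, adjusted p = 4.66e-23) and 3.43 (SE 0.058, adjusted p = 9.65e-29). Its Control mean of 6.03 was near background, as were those of Osi6 in both polyQ lines, 6.19 and 6.36, and of bw in A66QC, 6.16. In Atro the same genes differed from Control by -1.50 (SE 0.10) for bw, -2.03 (SE 0.092) for retinin, -0.93 (SE 0.092) for Pdh, -1.93 (SE 0.14) for Osi6, -1.48 (SE 0.10) for pkm, -1.76 (SE 0.071) for sad, -0.96 (SE 0.09) for rdhB, -0.38 (SE 0.07) for dmGlut and 2.42 (SE 0.058) for lncRNA:CR42646.

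**Figure D3:**
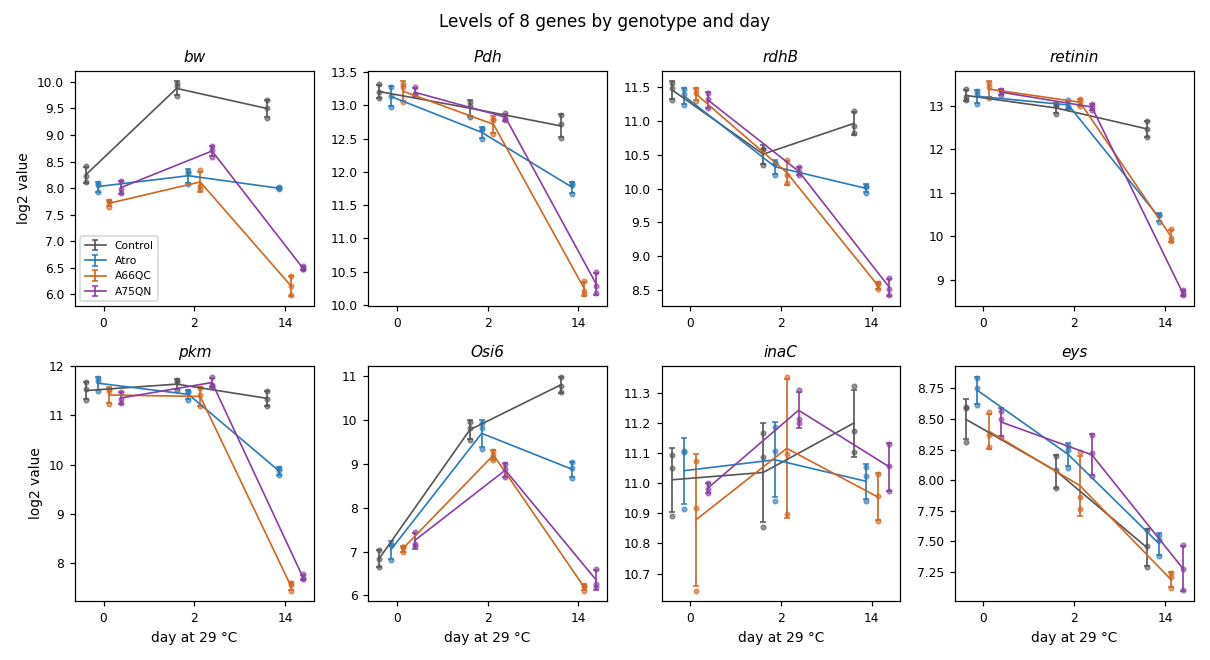
Log2 value of 8 genes by day at 29 °C (categories, not to scale in time) and genotype, with 1 point per array and lines through the group means, error bars SD (n = 3). The bw mean of Control at day 14 was 9.50, against 6.16 in A66QC and 6.49 in A75QN, while the photoreceptor genes inaC and eys differed by -0.24 and -0.26 in A66QC against Control.

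Eye pigment genes as a list were lower than in Control at day 14 in 12 of 20 cases in A66QC (0 higher and 13 lower adjusted over the list alone), 10 in A75QN (1 higher and 14 lower adjusted over the list alone) and 2 in Atro (0 higher and 2 lower adjusted over the list alone), with none called higher. With quantile normalization 6 were lower and 2 higher in A66QC, and 9 lower and 1 higher in A75QN. The eye regulator lz stood at -1.0 (SE 0.072) in A66QC and -0.81 (SE 0.072) in A75QN, near background in both lines, and Pu, the first enzyme of pteridine synthesis, at -1.02 (SE 0.13) and -0.86 (SE 0.13). Camera gave adjusted p = 1.16e-05 in A66QC, 9.23e-07 in A75QN and 0.00328 in Atro, and adjusted p = 0.435, 0.574 and 0.947 with an estimated correlation. Phototransduction and rhodopsin genes were lower in 18 of 33 cases in A66QC (0 higher and 21 lower adjusted over the list alone), 11 in A75QN, where 1 was higher (1 higher and 14 lower adjusted over the list alone), and 6 in Atro, where 2 were higher (2 higher and 10 lower adjusted over the list alone). The lipid phosphatase gene laza stood at -1.55 (SE 0.10) and -1.82 (SE 0.10), and ninaB, which makes the visual chromophore precursor, at -1.10 (SE 0.088) and -1.09 (SE 0.088) in A66QC and A75QN. With quantile normalization 14 were lower and 2 higher in A66QC, and 8 and 3 in A75QN. In Atro, pinta stood at -0.74 (SE 0.071), after -0.40 (SE 0.071) at day 0, and ninaG at 0.40 (SE 0.049). Here camera gave adjusted p = 4.13e-08, 2.54e-07 and 9.42e-06 in A66QC, A75QN and Atro, and adjusted p = 0.435, 0.729 and 0.947 with an estimated correlation. The 8 photoreceptor markers, which include inaC, trp and eys, moved little by comparison. Their median difference from Control was -0.16 in A66QC, with none called by limma (0 higher and 0 lower adjusted over the list alone), and -0.15 in A75QN, with chp called lower at -0.30 (SE 0.10, adjusted p = 0.0415) (0 higher and 1 lower adjusted over the list alone). Camera gave adjusted p = 0.328 and 0.110 for them, and adjusted p = 0.817 and 0.729 with an estimated correlation. The A75QN list passed the threshold without Control replicate 3. These medians were -0.046 and -0.011 with quantile normalization and turned to 0.0042 and 0.051 with cyclic loess. The chp call was lost in both scalings, without Control replicate 2, without A75QN replicate 1 or 2, and without the arrays of outlying spread. In A66QC, inaC, at -0.24 (SE 0.10, adjusted p = 0.0759), was called lower with the replicate number as a block, with array weights or in a fit of the 6 compared arrays, and eys, at -0.26 (SE 0.11, adjusted p = 0.0987), in that fit and without Control replicate 1.

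Genes of the Fat and Hippo pathway were lower than in Control at day 14 in 10 of 21 cases in A66QC (0 higher and 10 lower adjusted over the list alone) and 6 in A75QN (0 higher and 9 lower adjusted over the list alone). The glypican gene dlp stood at -1.27 (SE 0.073) and -1.03 (SE 0.073), after -0.50 (SE 0.073) in A75QN at day 0, and the apical polarity gene crb at -0.56 (SE 0.092) and -0.44 (SE 0.092). The camera test gave adjusted p = 6.63e-05 and 0.00532, and adjusted p = 0.435 and 0.729 with an estimated correlation. The list call of A75QN was also lost with quantile normalization and among the brighter probe sets alone. With quantile normalization 6 and 2 members were lower. The gene ft was not analysed here. Neuron and synapse genes were lower in 31 of 44 cases in A66QC (0 higher and 38 lower adjusted over the list alone), with nSyb, a synaptic vesicle SNARE, at -0.72 (SE 0.10) and fne at -0.67 (SE 0.10). At day 0 they had stood at -0.61 (SE 0.10) and -0.65 (SE 0.10). Their test gave adjusted p = 6.91e-10 by camera, and adjusted p = 0.435 with an estimated correlation. With quantile normalization 18 were lower.

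Counted over all probe sets at day 14, 349 were higher and 435 lower in Atro than in Control, 783 and 2582 in A66QC, and 1088 and 1839 in A75QN. These splits depended on the scaling and on dim probe sets. Among the brighter probe sets alone 327 were higher and 456 lower in Atro, 313 and 2772 in A66QC, and 230 and 1871 in A75QN. With quantile normalization they were 853 higher and 696 lower in Atro, 1457 higher and 1309 lower in A66QC and 1372 higher and 1165 lower in A75QN. Of the 3365 A66QC calls, 1638 held in the same direction in all 3 scalings, as did 1413 of the 2927 A75QN calls. The A66QC total became 1459 without Control replicate 2 and 1878 without A66QC replicate 2. The A75QN total became 1154 without Control replicate 2, 1619 without A75QN replicate 2 and 1930 without A75QN replicate 3. The Atro total of 784 became 501 without Atro replicate 2. The GAPDH 3'-minus-5' difference at day 14 was 2.32 in Control, 2.53 in Atro, 2.66 in A66QC and 2.31 in A75QN.

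Against Atro at day 14, both polyQ lines also held less message of bw and Pdh. Osi6 was lower at -2.69 (SE 0.14, adjusted p = 2.29e-15) in A66QC and -2.52 (SE 0.14, adjusted p = 1.08e-14) in A75QN, pkm at -2.35 (SE 0.10) and -2.16 (SE 0.10), bw at -1.84 (SE 0.10) and -1.50 (SE 0.10), and Pdh at -1.52 (SE 0.092) and -1.45 (SE 0.092). Near background were Osi6 in both polyQ lines and bw in A66QC. Cpr72Ec was lower at -1.97 (SE 0.12) and -1.99 (SE 0.12). Eye pigment genes were lower in 6 of 20 cases in A66QC (1 higher and 7 lower adjusted over the list alone) and 5 in A75QN, where 1 was higher (1 higher and 7 lower adjusted over the list alone). Camera gave adjusted p = 0.000179 and 0.000675 for this list, and adjusted p = 0.505 and 0.678 with an estimated correlation. In A66QC, 8 of 21 Fat and Hippo pathway genes were lower (0 higher and 9 lower adjusted over the list alone), such as lft at -0.59 (SE 0.067), with adjusted p = 3.36e-05 by camera, and adjusted p = 0.505 with an estimated correlation. In A75QN, 18 of 83 cytochrome P450 genes were lower and 1 higher (5 higher and 27 lower adjusted over the list alone), such as Cyp6t1 at -0.81 (SE 0.088), with adjusted p = 0.00138 by camera, and adjusted p = 0.678 with an estimated correlation. Cyp6t1 had stood at -0.58 (SE 0.088) against Control in A75QN at day 0. In all, 131 probe sets were higher and 969 lower in A66QC, or 545 higher and 676 lower with quantile normalization, and 60 and 1082 among the brighter probe sets alone. Its total of 1100 became 601 and 664 without Atro replicate 1 and 3, and 564 without A66QC replicate 2. A75QN had 519 higher and 1225 lower, or 1204 higher and 1187 lower with quantile normalization, and 236 and 1309 among the brighter ones. Its total of 1744 became 1123 without Atro replicate 1 and 1038 without A75QN replicate 2.

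The polyQ lines shared many of these differences. Called the same way in both lines against both Control and Atro at day 14 were 278 probe sets, 258 lower and 20 higher. With quantile normalization 193 were lower and 30 higher, and 178 of the 258 stayed lower in all 3 scalings. Among the brighter probe sets alone 291 were lower and 3 higher. In 42 of the 258 the difference from Control was at least 1 on the log2 scale in both lines. Beyond the genes already named, the shared calls held the eye regulators eya, at -1.07 in A66QC and -0.98 in A75QN, and gl, at -0.46 and -0.51, and the adhesion gene rst, at -1.0 and -0.76. The largest adjusted p of their 4 comparisons was 5.83e-08 for eya, 0.000631 for gl and 0.000247 for rst. These 3 were picked after their values were seen. In 220 genes the representative probe set had a shared lower call. Among these 220, 5 of the 33 members of the phototransduction list stood against 0.606 by chance (one-sided hypergeometric test over 11982 genes, adjusted p = 0.00595). This test takes the genes as independent, and the list's calls in A66QC and A75QN against Control were lost with an estimated correlation (adjusted p = 0.435 and 0.729). The 5 were gl, laza, ninaB, rdgB and retinin, of which gl is a regulator and retinin a lens gene, so the count does not speak for phototransduction alone. Of 20 eye pigment genes, 4 were in it, bw, g, Pu and the regulator lz, against 0.367 by chance (adjusted p = 0.00595), with the same limit (adjusted p = 0.435 and 0.574 with an estimated correlation). Of the 258 probe sets, 50 were also called lower in Atro than in Control, 5 higher, and 203 were not called. At day 0, 51 had been called lower than in Control in A66QC, 49 in A75QN and 23 in both. The change since day 0 was called more negative than in Control for 144 in A66QC, 120 in A75QN and 106 in both, which need not be a fall. In Control, whose arrays enter this comparison too, 127 of the 258 had risen and 49 had fallen by day 14. Paired otherwise, A66QC and Atro shared 123 calls against A75QN and Control, and A75QN and Atro shared 22 against A66QC and Control.

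Comparisons that share control arrays also share chance values, so their overlap is given beside simulated values. Against Control at day 14, A66QC and A75QN had 248 higher and 997 lower calls in common and 51 opposite, where independent lists would share 45.4 and 253. Simulated unchanged groups with a common Control shared 0 calls in 20 simulations. That outcome was fixed in advance, since unchanged groups rarely pass an adjusted threshold, so the 0 is no baseline for the overlap. The simulated arrays were drawn independently, so the values below lack any structure common to whole arrays. The covariance of the log2 differences was 0.0311, against 0.00291 simulated, and their correlation across probe sets 0.705, against 0.498. Against Atro, the lines had 29 higher and 423 lower calls in common, where independent lists would share 3.62 and 63.2, and 27 opposite. Here the covariance was 0.0130 against 0.00292 simulated, while the correlation, 0.503, was close to the 0.499 of unchanged groups. With 3 control arrays the controls could not be split, so part of the excess may come from the shared controls.

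The polyQ lines also differed from each other. Tektin-C was lower in A66QC at -2.18 (SE 0.10, adjusted p = 5.89e-16) at day 2 and -2.19 (SE 0.10, adjusted p = 2.45e-16) at day 14, and the drosomycin-like gene Drsl4 at -1.62 (SE 0.15) and -1.86 (SE 0.15). Tektin-C was near background in A66QC on all days. Against Control at day 0, where it was near background too, it had stood at 2.16 (SE 0.10) in A75QN, and Drsl4 at -0.75 (SE 0.15) in A66QC and 0.23 (SE 0.15) in A75QN. At day 14, retinin was higher in A66QC than in A75QN by 1.30 (SE 0.092, adjusted p = 1.45e-11). The larval serum protein gene Lsp2 was higher in A66QC by 2.29 (SE 0.50, adjusted p = 0.00240) and CheA7a, near background in A75QN, by 1.78 (SE 0.22). Of 13 fat body and yolk markers, 5 were higher in A66QC and none lower at day 14 (8 higher and 0 lower adjusted over the list alone), such as fit at 1.17 (SE 0.18), with adjusted p = 2.24e-06 by camera, and adjusted p = 0.473 with an estimated correlation. Of 15 haemocyte markers, 7 were higher and 1 lower (9 higher and 1 lower adjusted over the list alone), with Hml at 0.43 (SE 0.077) and NimC1 at -0.80 (SE 0.10), after -0.48 (SE 0.10) against Control in A66QC at day 0. These had adjusted p = 0.000123 by camera, and adjusted p = 0.802 with an estimated correlation. Neuron and synapse genes at day 2 were lower in A66QC in 5 of 44 cases (0 higher and 13 lower adjusted over the list alone), or 17 with quantile normalization, with adjusted p = 1.99e-10 by camera, and adjusted p = 0.929 with an estimated correlation. The GAPDH 3'-minus-5' difference at day 2 was 2.54 ± 0.14 in A66QC and 2.28 ± 0.058 in A75QN, and at day 14 2.66 ± 0.075 and 2.31 ± 0.18 (SD, n = 3). At day 2, 260 probe sets were higher and 280 lower in A66QC. This total of 540 became 310 and 899 without A66QC replicate 2 and 3, 293 and 314 without A75QN replicate 2 and 3, and 1702 with quantile normalization. At day 14, 662 were higher and 874 lower, a total of 1536 that became 1018 and 1023 without A66QC replicate 1 and 2, and 3131 with quantile normalization. The higher spike-in signal lay on the A75QN arrays on both days.

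**Figure D4:**
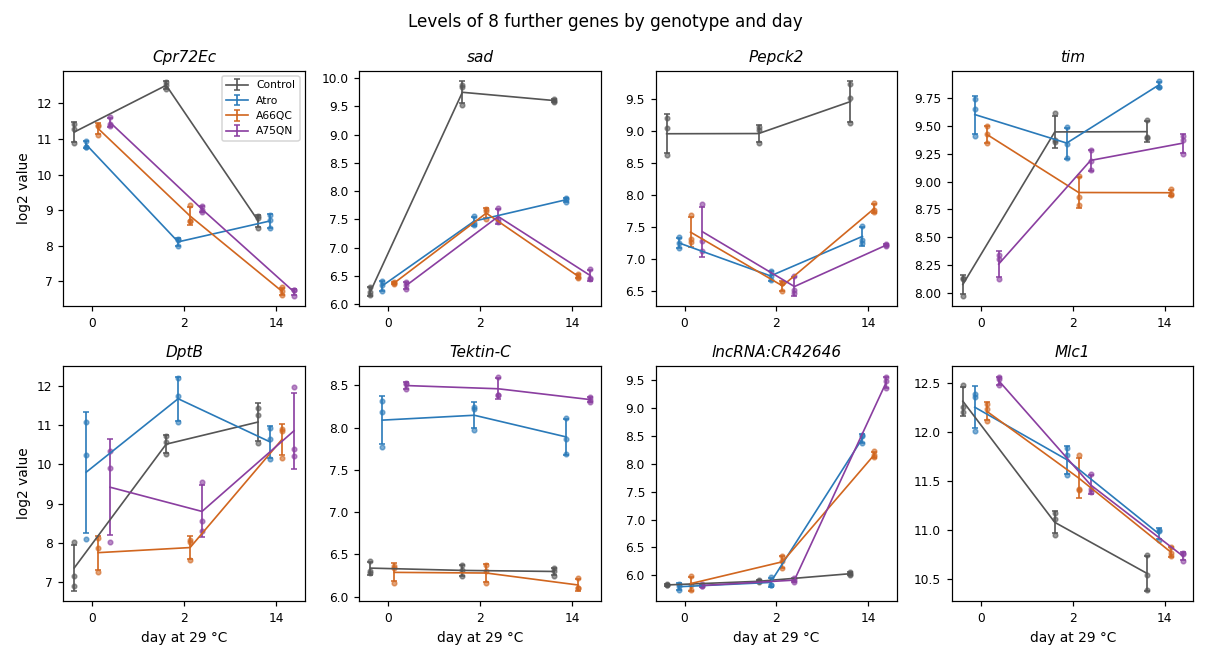
Log2 value of 8 further genes by day at 29 °C (categories, not to scale in time) and genotype, with 1 point per array and lines through the group means, error bars SD (n = 3). Tektin-C averaged 7.89 in Atro and 8.33 in A75QN at day 14, against 6.30 in Control and 6.14 in A66QC.

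Comparing each line's change from day 0 to day 14 with that of Control removes constant differences between stocks. Relative to the change in Control, Osi6 changed by -2.13 (SE 0.19, adjusted p = 5.76e-09) in Atro, -4.85 (SE 0.19, adjusted p = 3.25e-18) in A66QC and -4.86 (SE 0.19, adjusted p = 2.38e-18) in A75QN. For bw the differences in change were -1.28 (SE 0.14), -2.81 (SE 0.14) and -2.77 (SE 0.14), for retinin -2.01 (SE 0.13), -2.60 (SE 0.13) and -3.83 (SE 0.13), and for sad -1.86 (SE 0.10), -3.26 (SE 0.10) and -3.20 (SE 0.10). In the polyQ lines pkm differed by -3.74 (SE 0.14) and -3.49 (SE 0.14) and Pdh by -2.45 (SE 0.13) and -2.36 (SE 0.13). The change of lncRNA:CR42646 was larger by 2.45 (SE 0.082), 2.11 (SE 0.082) and 3.44 (SE 0.082). It was near background in Control and at day 0 in all lines, sad at day 0 in all genotypes, Osi6 at day 14 in both polyQ lines and bw at day 14 in A66QC, so the sizes of these differences are uncertain. Eye pigment genes had a more negative change than in Control in 4 of 20 cases in Atro (0 higher and 4 lower adjusted over the list alone), 5 in A66QC (0 higher and 8 lower adjusted over the list alone) and 5 in A75QN (0 higher and 7 lower adjusted over the list alone). The camera test gave adjusted p = 1.68e-05, 5.62e-08 and 4.39e-07, and adjusted p = 0.480, 0.466 and 0.666 with an estimated correlation. Phototransduction genes did so in 3 of 33 cases in A66QC (1 higher and 15 lower adjusted over the list alone) and 5 in A75QN (0 higher and 8 lower adjusted over the list alone), with adjusted p = 2.36e-09 and 1.73e-07 by camera, and adjusted p = 0.723 and 0.799 with an estimated correlation. Proteasome genes in Atro did so in 4 of 28 cases (1 higher and 22 lower adjusted over the list alone), with adjusted p = 1.16e-13 by camera, and adjusted p = 0.432 with an estimated correlation. At day 0, before induction, 22 of these 28 had been called higher in Atro than in Control. The more negative change thus starts from a raised level and need not reflect the transgene. In all, 126 probe sets changed more positively and 270 more negatively in Atro, 95 and 335 in A66QC, and 142 and 438 in A75QN. Quantile normalization gave 425 more positive and 392 more negative in Atro, 364 and 470 in A66QC, and 846 and 764 in A75QN. The Atro total of 396 became 253 without Atro day 14 replicate 2.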

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

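The tests of the 3 patterns weighed here and the exchange on day 14 were chosen after the results were seen, while the splits of the samples were planned. The change from day 0 to day 14 differed from that of Control in 396 probe sets in Atro, 430 in A66QC and 580 in A75QN, by limma's test of the difference in change. The splits of the samples leave open whether chance gives such counts. The draws of 100 hold 4, 9 and 12 splits with as many calls, the real one included, and the highest other gave 874, 5760 and 4685. These splits mix the genotypes within a day, so they hold genotype differences that need not change with time. Exchanging the genotypes on day 14 alone, which adds up the differences of both days, gave 1248, 5760 and 4685 calls and points to that structure of the samples. The limma values of single genes do not rest on these splits.

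By the same test of single genes, the change of Osi6 differed from that in Control by -2.13 in Atro, -4.85 in A66QC and -4.86 in A75QN. Those of bw were -1.28, -2.81 and -2.77, those of retinin -2.01, -2.60 and -3.83, those of sad -1.86, -3.26 and -3.20, and those of lncRNA:CR42646 2.45, 2.11 and 3.44. For pkm they were -3.74 in A66QC and -3.49 in A75QN, and for Pdh -2.45 and -2.36. The lncRNA was near background in Control and at day 0 in all lines, sad at day 0 in all genotypes, Osi6 at day 14 in both polyQ lines and bw at day 14 in A66QC, so the sizes of these differences are uncertain. Poly-A spike-ins, which no comparison uses, averaged 13.23 in A75QN at day 2 and 13.29 at day 14, above Control at 10.4 and 10.6.

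The first pattern is the set of 42 probe sets, bw, Pdh and retinin among them, that had a shared lower call at day 14, so were lower than in both Control and Atro, and lay 1 or more below Control on the log2 scale in both polyQ lines. Between-array scaling as the whole cause of these 42 is argued against by the 40 that kept their shared lower call with quantile and cyclic loess normalization. The 42 were picked for large differences from Control, and of all 258 shared lower calls 178 were kept. Such a difference need not be a fall in the polyQ lines, as in Control 127 of the 258 had risen by day 14. Another 49 had fallen there. In Control sad had risen by 3.38 and bw by 1.25 since day 0, while Pdh had changed by -0.52. The 42 cannot test the spike-in difference of the A75QN arrays, as a shared call already asks for A66QC below Atro. Over all probe sets, A75QN against Control and A66QC against Atro, with no array in common, shared 242 lower calls with quantile normalization. That is 5.77 times the 42.0 of independent lists, but both comparisons take each probe set's spread from one fit. The ratio is therefore no test of the 42. An equal loss of all eye cell types as the source of differences this large is argued against by the 8 photoreceptor markers measured. The lowest of them stood at -0.30 in either line, against medians of -1.64 and -1.50 for the pattern, while eys had a Control level of 7.45 and inaC one of 11.2. The pattern was picked for its differences from Control, though, and the photoreceptor medians were -0.16 and -0.15, near those of the unpicked eye pigment list. A smaller equal loss is thus not excluded. Only 8 of the 16 photoreceptor markers written were measured, and the 33 genes of the phototransduction list were not part of this test. Of those 33, 5 had shared lower calls, among them laza at -1.55 in A66QC and -1.82 in A75QN against Control. More were called lower than in Control in each line. The 8 markers thus do not show that all photoreceptor genes were spared. A response to the Atrophin transgenes, not necessarily to the expansion, and a loss of accessory eye cells such as pigment cells both stay open. The eye pigment genes, some active in other cells too, had medians of -0.24 and -0.26, with Pu at 10.7 in Control, 9.72 in A66QC and 9.87 in A75QN. In Atro, with the wild-type transgene, bw stood at -1.50, retinin at -2.03 and Pdh at -0.93 against Control at day 14, but Cpr72Ec of the pattern at -0.0061. At day 2, though, Cpr72Ec had stood at -4.40 in Atro against Control, and in Control it changed by -2.49 from day 0 to day 14. Its value at day 14 thus does not show that Atro left this gene unchanged. Of the 258 shared lower calls, 50 were also called lower in Atro and 203 were not called. How strongly each transgene was expressed is not known here.

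The second pattern is the spike-in signal of the A75QN arrays of days 2 and 14. Brighter arrays throughout are argued against by the hybridization controls, which differed by -0.0220 between these 6 arrays and the other 30. More spike-in RNA added before labelling stays open, since the rise of the spike-ins by 2.77 is the pattern itself and no test here bears on its source. Whether these arrays were labelled on another day is not given in the sources used here, and a labelling batch and the genotype cannot be told apart in them. No biological explanation was tested.

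The third pattern is the excess of lower calls in the polyQ lines against Control at days 0 and 14, where 23.0% and 23.3% of the A66QC calls and 28.0% and 37.2% of the A75QN calls were higher. A spread of values that differs between arrays is a candidate source. The median change of the dimmest quartile of probe sets exceeded that of the brightest in all 4 comparisons, by at least 0.149 and at most 0.229. A true loss of abundant transcripts in these lines could give the same difference and stays open. Quantile normalization gives all arrays one spread whatever the cause, so its counts do not tell them apart. The excess was not limited to these comparisons. Against Atro at days 2 and 14, 20.6% and 11.9% of the A66QC calls and 33.2% and 29.8% of the A75QN calls were higher. Against Control at day 2 the shares were 35.0% and 35.4%. The median array SD of a group was 1.57 to 1.60 in Control and Atro and 1.51 to 1.53 in the polyQ lines. Asking for calls against Atro as well thus does not guard the shared lower calls from this difference in spread.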

How the results depend on the processing

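The tests without the arrays of outlying spread and with A66QC alone were chosen after the results were seen. Under the alternatives that were run, no named gene or list test past the threshold turned its direction, though medians of lists not called did, as for the chaperones. The totals of the 22 counts stayed within 1.5 times with the brighter probe sets alone and with the trended and robust prior. The higher calls of 5 counts at day 14 did not among the brighter probe sets. There 313 were higher and 2772 lower in A66QC than in Control (as deposited 783 and 2582), 230 and 1871 in A75QN (1088 and 1839). Against Atro they were 60 and 1082 in A66QC (131 and 969), and 236 and 1309 in A75QN (519 and 1225). Shared calls were 3 higher and 291 lower, where all probe sets gave 20 and 258. With the prior, of the higher and lower calls only the shared higher ones at day 2 moved by over 1.5 times, from 0 to 1. Of 452 named genes in their comparisons, 450 kept their side of the threshold with quantile normalization, 446 with array weights, 435 in fits of the compared groups alone and 442 with the trended prior, while 429 lie among the brighter probe sets and kept theirs there. Of all named genes, 35 changed side without some single array. Of 46 tests of a list in a comparison described, 42 lost their call with an estimated correlation and 4 were not called with either. The counts printed next moved by over 1.5 times, and the cause was not tested. Dim probe sets near the background limit what these arrays can show.

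Quantile normalization gave, against Control, 1625, 1588 and 1549 for Atro at days 0, 2 and 14, 1430 for A66QC at day 2 and 2223 for A75QN at day 2. Counts were, against Atro, 435 for A66QC at day 2 and 1031 for A75QN at day 2. It gave 1702 for A66QC against A75QN at day 2, 3131 for A66QC against A75QN at day 14, 817 for the change in Atro against that in Control, 834 for the change in A66QC against that in Control, 1610 for the change in A75QN against that in Control and 35 for the shared calls at day 2. Cyclic loess normalization gave, against Control, 1680, 1548 and 1655 for Atro at days 0, 2 and 14, 1423 for A66QC at day 2 and 2129 for A75QN at day 2. With it they were, against Atro, 369 for A66QC at day 2 and 965 for A75QN at day 2. This scaling gave 1599 for A66QC against A75QN at day 2, 2999 for A66QC against A75QN at day 14, 877 for the change in Atro against that in Control, 859 for the change in A66QC against that in Control, 1410 for the change in A75QN against that in Control and 34 for the shared calls at day 2.

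Array weights gave, against Control, 1875, 1878 and 1329 for Atro at days 0, 2 and 14, 4096 and 5471 for A66QC at days 0 and 2 and 4036 and 3111 for A75QN at days 0 and 2. Weighted counts were, against Atro, 4538 and 3674 for A66QC at days 2 and 14 and 1909 and 3169 for A75QN at days 2 and 14. The weights gave 4539 for A66QC against A75QN at day 2, 847 for the change in Atro against that in Control, 223 for the shared calls at day 2 and 460 for the shared calls at day 14. Fits of the compared groups alone gave, against Control, 379 for Atro at day 0, 1154 and 400 for A66QC at days 0 and 2 and 1374 and 1755 for A75QN at days 2 and 14. Their counts were, against Atro, 44 and 3085 for A66QC at days 2 and 14. Such fits gave 257 for the change in Atro against that in Control and 19 for the shared calls at day 2.

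Without the 6 arrays of outlying spread the counts were, against Control, 2955 for A66QC at day 2 and 3586 and 1621 for A75QN at days 0 and 2. Without them they were, against Atro, 2894 and 2430 for A66QC at days 2 and 14 and 935 and 3112 for A75QN at days 2 and 14. Others were 1891 for A66QC against A75QN at day 2, 2561 for A66QC against A75QN at day 14 and 108 for the shared calls at day 2. With A66QC alone the shared calls were 47 at day 2 and 764 at day 14, and as fewer conditions are asked for, these cannot be lower than the shared counts.

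Leaving out each replicate in turn gave 490 to 989 for Atro against Control at day 0, 974 to 2679 for A66QC against Control at day 0, 656 to 1628 for A75QN against Control at day 0, 533 to 931 for A75QN against Control at day 2. It gave 501 to 794 for Atro against Control at day 14, 1459 to 3737 for A66QC against Control at day 14, 1154 to 3070 for A75QN against Control at day 14, 41 to 189 for A66QC against Atro at day 2. Further ranges were 208 to 444 for A75QN against Atro at day 2, 564 to 885 for A66QC against Atro at day 14, 1038 to 1785 for A75QN against Atro at day 14, 293 to 899 for A66QC against A75QN at day 2. The last were 1018 to 1286 for A66QC against A75QN at day 14, 253 to 534 for the change in Atro against that in Control. The fit then holds fewer arrays, and a group of 2 is assumed to vary like the others.

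The labels do not tell whether the replicate numbers pair the arrays, and the correlations show little sign of it. Deviations from the group means correlated by 0.0316 on average between arrays of the same number, from -0.599 to 0.678, and by -0.0156 between other numbers, and 13 of 36 arrays correlated best with their own number. With the number as a block, Control gave 4352 calls at day 2 and 6086 at day 14. Against Control at days 0, 2 and 14 the block gave 866, 728 and 842 for Atro, 2254, 702 and 3666 for A66QC and 1439, 966 and 3189 for A75QN. Against Atro at days 2 and 14 it gave 103 and 1243 for A66QC and 426 and 1913 for A75QN. Between the polyQ lines it gave 609 and 1692, for the changes in Atro, A66QC and A75QN 425, 445 and 625, and for the shared calls 12 and 308. The block moved no count by 1.5 times and no list call, and of the named genes only inaC in A66QC at day 14 changed side, to a lower call. All counts except the shared one at day 2 were higher with the block than without it. The number may thus take up some of the spread, and a pairing is not excluded.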

Other observations

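The tests of differences held on all days, the other pairings of genotypes and the choice of lists described here came after the results were seen, while the splits of the samples were planned. Some genes differed from Control on all 3 days in all 3 transgenic lines, also at day 0 before induction. They were 13 higher and 28 lower probe sets. Simulated unchanged groups gave at most 0, which was fixed in advance, since such groups rarely pass an adjusted threshold. Pepck2 differed by 1.53 to 2.39 on the log2 scale over the 9 comparisons, lower in each, TkR86C by 1.18 to 1.37 and the noncoding RNA lncRNA:CR32553 by 1.17 to 1.98. Hsc70-2, of the Hsp70 family, was lower by 0.80 to 0.91 on all days, near background in all lines. On the higher side, gol differed by 0.54 to 1.21 and kek5, near background in Control, by 0.51 to 0.89. Counted in each line whatever the other lines did, Atro had 75 higher and 67 lower on all days, A66QC 75 and 150, and A75QN 50 and 131. The lines share their Control arrays, so part of this overlap cannot be split from them.

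Chaperone genes moved little at day 14. Of 21 heat-shock and chaperone genes, 1 was higher in A66QC than in Control, P58IPK at 0.27 (SE 0.088), a call lost without replicate 1 or 3 of either group, and 1 was lower, Hsc70-2 at -0.83 (SE 0.055) (1 higher and 1 lower adjusted over the list alone). The sizes of the Hsc70-2 differences are uncertain, as its levels in the lines were near background. In A75QN 3 were lower and none higher (0 higher and 3 lower adjusted over the list alone), with Hsc70-2 at -0.80 (SE 0.055), and without Control replicate 3 the list passed the threshold. Their lists had adjusted p = 0.388 and 0.0954 by camera, and adjusted p = 0.868 and 0.729 with an estimated correlation. Quantile normalization turned the list medians from -0.065 and -0.088 to 0.043 and 0.083, and cyclic loess to 0.12 and 0.067. Glia genes were lower in A66QC than in Control in 12 of 27 cases (0 higher and 15 lower adjusted over the list alone), with moody, a receptor of the blood-brain barrier, at -0.84 (SE 0.093) and the gap junction gene Inx2 at -0.79 (SE 0.13). They had adjusted p = 0.000743 by camera, and adjusted p = 0.571 with an estimated correlation, and with quantile normalization 9 were lower and 4 higher. Sugar metabolism genes were lower in A75QN in 11 of 19 cases (0 higher and 14 lower adjusted over the list alone), with Pgm1 at -0.49 (SE 0.075) and Tpi at -0.48 (SE 0.081). They had adjusted p = 0.000300 by camera, and adjusted p = 0.729 with an estimated correlation, and with quantile normalization 7 were lower and 2 higher.

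The shared calls of the polyQ lines exceeded those of the other 99 drawn splits of a day's 12 arrays. The real count and the highest other were 278 and 243 at day 14 and 12 and 0 at day 2, and 1 of 100 splits, the real one, gave as many. Chance can be excluded by this only in that the arrays do not fall into groups at random, since the splits mix the genotypes and do not test which genotypes share. Exchanging whole groups bears on that, but it leaves too few pairings for a share under 0.05. At day 14, A66QC and Atro against A75QN and Control shared 123 calls, and A75QN and Atro against A66QC and Control 22, both below the polyQ lines. At day 2 these pairings gave 59 and 8, the first above the polyQ lines, so the count at day 2 does not set them apart.

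The comparisons of 3 against 3 arrays have 10 splits each, too few for a share under 0.05. The real count and the highest of the other splits were 4164 and 0 for Control at day 2, 5904 and 0 for Control at day 14, 821 and 220 for Atro against Control at day 0, 2038 and 20 for A66QC and 1321 and 0 for A75QN. At day 2 against Control they were 681 and 0 for Atro, 646 and 3329 for A66QC and 878 and 0 for A75QN, and at day 14 784 and 3, 3365 and 0 and 2927 and 17 in the same order. Against Atro they were 97 and 4443 for A66QC and 397 and 0 for A75QN at day 2, and 1100 and 3 and 1744 and 0 at day 14. Between the polyQ lines they were 540 and 0 at day 2 and 1536 and 2 at day 14. In A66QC at day 2, 2 of 10 splits against Control and 2 of 10 against Atro gave as many calls as the real one. The larger count came from the split that sets A66QC replicates 1 and 2 together with replicate 2 of Control or of Atro. It is several times the real count, which points to a structure of the samples that the groups do not give. A66QC replicate 3 and replicate 2 of Control and of Atro at day 2 are among the 6 arrays of outlying spread, and without those 6 arrays the counts were 2955 against Control and 2894 against Atro.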
